A study of Mus musculus with 4 samples.

How the data were processed

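Single-cell RNA was profiled from the tarsal plate, the part of the eyelid that holds the meibomian glands, of male C57Bl/6 mice aged 6 months. Per the labels' protocols, tissue was digested with collagenase and hyaluronidase and then trypsin, libraries were made on the 10x Genomics Chromium platform, and paired reads of 150 bp were sequenced on an Illumina NovaSeq sequencer. Wild-type replicates 1 and 2 (run 1) pooled 3 mice each, and wild-type replicate 3 and the Awat2 knockout library (run 2) pooled 4 littermates each. The deposited values are UMI counts per gene and cell barcode, made with Cell Ranger 3.1.0 against mm10, per the submitters' processing notes. The release of the gene annotation used by the authors was not given in the sources used here, and 32235 of the 32285 gene IDs (99.8%) were found in GENCODE mouse release M21, from which positions were taken. A symbol shared by more than 1 gene ID (38 symbols) was kept apart by ID. How reads shared between paralogs such as Awat1 and Awat2 entered the counts or were lost from them was not examined.

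Expression was analysed in the 3 wild-type libraries, and the expression of the knockout library (15930 barcodes) was not analysed here, so no genotypes were compared. The wild-type libraries held 41305015, 37518556 and 134363492 UMIs in replicates 1, 2 and 3, with median depths of 7382, 9308.5 and 9130.5 UMIs and 2115, 2497.5 and 2546 genes per barcode. Pairs of libraries shared 3, 19 and 13 barcodes, and their median absolute log2 difference per gene (0.152, 0.313 and 0.197) lay above that from counting (0.0214, 0.0171 and 0.0178), so the libraries were treated as separate samples. Barcodes with under 500 UMIs, under 250 genes or over 20% mitochondrial UMIs were removed (244, 204 and 550). Doublets were scored against simulated ones in the manner of Scrublet, with 2 simulated doublets per barcode. The automatic threshold called 0.0665%, 0.0931% and 2.56%, where under 0.5% was taken as failed, so it failed in replicates 1 and 2. In all 3 libraries an expected rate of 0.8% per 1000 barcodes (3.61%, 2.58% and 9.36%) was used instead. Barcodes scoring strictly above the quantile at that rate were removed (152, 67 and 1045 barcodes).

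Genes were split at random (seed 1) into 16042 for clustering, with all naming markers, and 16243 for testing, with all fixed lists, so that no tested gene defined a cluster. The 2000 most variable clustering genes were reduced to 30 principal components, and cells were joined to 10 neighbours in each library, weighted by shared neighbours. The Leiden method at resolution 1 gave 30 clusters of 18165 cells, and the meibocyte-like cells were clustered again at resolution 0.5. Clusters and classes were rebuilt here and are not the authors' labels. A cluster took the name of 1 of 24 classes, from 146 marker genes (144 found), when at least 3 markers were detected in at least 10% of its cells and the mean log2 fold of its markers over the other clusters was above 0 and led the next class by at least 1. It stayed unnamed when another class had more markers among its 10 leading genes, or when its median depth was under 1/3 of the library median with no own marker leading. Of the 30 clusters 8 took no name, the Krt79-high cluster included. A ductal-epithelial class was among the 24, and no cluster met its rule. The Krt79-high cluster is the cluster with the highest Krt79 CPM among those not named meibocyte-like.

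The groups, lists, markers, thresholds, planned comparisons and other settings were chosen before the data were examined. The naming rule was set after cluster marker levels, leading genes and levels of a few list genes, Awat2 among them, had been seen, but before any differential test, and it replaced an earlier rule on z-scores. The doublet removal at the expected rate was chosen after the automatic result was seen, and the 2 comparisons with the Krt79-high cluster replaced 2 planned comparisons with ductal-epithelial-like cells after the clusters were seen. Genes named in the observations on cycling and Rspo3-high cells were chosen after their values were seen.

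UMIs were summed per library and class with at least 20 cells, since cells are not replicates. Sums were normalised by TMM and tested with edgeR 4.0.16 (quasi-likelihood test, library as a block), and genes were called at an adjusted p under 0.05 (Benjamini-Hochberg over the genes of a comparison) and an absolute log2 fold change of at least 1. The sums of the 4 epithelial classes entered 1 fit and shared its spread. Those of the Krt79-high cluster or of fibroblast-like cells were added for their comparisons. The keratin comparison was fitted on the sums of all meibocyte-like subclusters. Residual degrees of freedom were 6 for the meibocyte-like against basal-epithelial-like and keratin comparisons and 8 for the others. A fold against a class with 0 UMIs is a lower bound against 3 counts over the class, and with 1 to 3 UMIs the ratio of pooled rates is given with its 95% counting interval. The 21 fixed lists (381 genes, 380 found) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and with an estimated correlation, with Benjamini-Hochberg adjustment over the 21 lists and 5 comparisons together. A list needed at least 3 tested members. The adjusted p at both correlations is given beside each call. Intervals cover counting error only.

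Genes were named by a rule: 12 fixed genes (11 of them Awat2, Awat1, Far2, Soat1, Dgat2, Elovl1, Elovl3, Elovl4, Elovl6, Ptch1 and Gli1, and 1 not reported here), the 8 with the largest change in each direction among called genes with at least 50 CPM and the same direction in every library, gene models without a symbol name left out, and up to 4 called members of each called list. The text gives a part of these, and the counts cover the rest. The gene and list tests were tested on simulated data, with 200 genes of the real libraries changed by known folds and a simulated list of 20 genes, before they were run on the real counts. Class sums were also permuted over other splits. Alternatives were RLE normalization, DESeq2 1.42.0, no low-count filter, no replicate block, sums of the compared classes alone, each replicate left out, at least 1000 UMIs, at most 10% mitochondrial UMIs, doublets kept, Leiden resolution 0.5, a plain graph with 30 neighbours, another random gene split, and, added later, unnamed clusters given their best class. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.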

Results

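The series profiled single cells of the mouse meibomian gland, the lipid-secreting gland of the eyelid, in wild-type mice and in mice lacking Awat2. Awat2 encodes an acyltransferase that joins fatty alcohols to fatty acids to make wax esters. Wild-type replicates 1, 2 and 3 and 1 Awat2 knockout library were listed, each a pool of 3 or 4 male mice aged 6 months. Expression was compared among cell classes of the 3 wild-type libraries, which pooled 10 mice, and the expression of the knockout library was not analysed here. Replicates 1 and 2 came from run 1, and replicate 3 came from run 2 with the knockout library, so run and replicate could not be separated.

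Wild-type replicate 1 held 4755 cell barcodes and 41305015 UMIs (unique molecular identifiers, counts of captured transcripts). Replicate 2 held 3428 barcodes and 37518556 UMIs, and replicate 3 held 12244 barcodes and 134363492 UMIs. Median depth per barcode was 7382, 9308.5 and 9130.5 UMIs in the same order. After filtering and removal of predicted doublets 4359, 3157 and 10649 cells were kept. Levels are given as CPM (counts per 1000000 counts) of the summed cells of a class in each library, as mean ± SD over the 3 libraries (n = 3). Log2 fold changes (log2FC) are given ± SE. This SE is the absolute log2FC over the square root of the quasi-likelihood F, not an error fitted directly. It is approximate and need not cover counting error where a class holds few UMIs. Where CPM of 2 classes are given together, the class named first in the comparison comes first.

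Awat2 (ENSMUSG00000031220, minus strand of chromosome X, 100402221 to 100442717 on mm10) was measured first, as the targeted gene of the series. In meibocyte-like cells, Awat2 reached 67.5, 39.4 and 29.6 CPM in wild-type replicates 1, 2 and 3. The Krt79-high cluster held 19.3, 12.3 and 12.1 CPM of Awat2 in the same order. Awat2 averaged 2.87 ± 0.64 CPM in suprabasal-epidermal-like cells, 0.393 ± 0.0809 CPM in fibroblast-like cells and 0.0859 ± 0.149 CPM in basal-epithelial-like cells (n = 3). At least 1 Awat2 UMI was found in 389 of 1481 meibocyte-like cells (26.3%, median depth 17420 UMIs) and in 107 of 910 cells of the Krt79-high cluster (11.8%, median depth 12667.5 UMIs). The matching share was 0.245% of 2852 fibroblast-like cells at a median depth of 5308.5 UMIs and 0.0957% of 1045 basal-epithelial-like cells at 5375 UMIs. Awat1, the neighbouring paralog on chromosome X (100572251 to 100578205), reached 1.04 ± 0.702 CPM in meibocyte-like cells (n = 3) and was too low to test.

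The cells formed 30 clusters, of which 22 were named by fixed marker genes. Fibroblast-like cells made up 15.3 ± 1.64% of cells (SD, n = 3 libraries), and meibocyte-like cells 8.24 ± 0.25%. Of the 2 meibocyte-like clusters, the larger was led by Plin2, Lcn2 and Pparg and the smaller by Scd1, Cidea and Paqr7. Basal-epithelial-like cells (5.73 ± 0.36%) were a single cluster led by Egfl6, Grem1 and Krtap17-1. Col17a1 was the only naming marker of that class among its 10 leading genes. Suprabasal-epidermal-like cells, led by Krt1 and Krt10, held 6.14 ± 0.48% of cells, and conjunctival-epithelial-like cells, led by Serpinb3a and Krt13, held 3.69 ± 1.26%. Cycling cells held 7.64 ± 0.98%, pericyte- or smooth-muscle-like cells 2.99 ± 0.90%, T- or NK-like cells 2.38 ± 1.00%, macrophage-like cells 2.18 ± 0.69% and endothelial-like cells 1.79 ± 0.32%. Schwann-like (0.492 ± 0.308%), melanocyte-like (0.368 ± 0.202%) and muscle-satellite-like cells (0.239 ± 0.0126%) were rarer. Immunoglobulin genes Iglc1, Igha and Jchain stood among the leading genes of the T- or NK-like cluster, and hemoglobin genes among those of the hair-follicle-like cluster led by Krt25 and Krt71.

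No cluster met the naming rule for ductal-epithelial-like cells. The cluster with the highest Krt79 (ENSMUSG00000061397, chromosome 15, 101929332 to 101940324), a keratin of pilosebaceous ducts, was led by Krtdap, Krt79, Car2 and Psapl1 and is called the Krt79-high cluster. It held 6.95% of cells in replicate 1 (95% Clopper-Pearson interval 6.21 to 7.75%), 8.14% in replicate 2 (7.21 to 9.15%) and 3.29% in replicate 3 (2.96 to 3.64%). With doublets kept these shares were 4.88%, 4.81% and 2.45%, under another random split of the genes 4.61%, 4.40% and 2.39%, and at Leiden resolution 0.5 they were 13.1%, 15.0% and 9.10%. At that resolution the cluster with the highest Krt79 held 2013 cells instead of 910 and met the rule for suprabasal-epidermal-like cells, so it was not the same cluster and no separate suprabasal-epidermal-like class was left. Hair-follicle-like cells held 3.60% of replicate 1 (3.07 to 4.20%), 5.57% of replicate 2 (4.80 to 6.43%) and 11.2% of replicate 3 (10.6 to 11.8%). At a minimum of 1000 UMIs per cell they held 1.41%, 2.49% and 7.11%, and under 4 further settings 1.26 to 1.38%, 2.39 to 2.50% and 6.78 to 7.06%. In each of these settings a cluster of 661 to 708 cells whose best class was hair follicle stayed unnamed. At Leiden resolution 0.5 clusters of 1038 and 569 cells took the hair follicle name. Beside the Krt79-high cluster, 7 clusters stayed unnamed in the reported grouping and held 30.7%, 27.8% and 31.1% of replicates 1, 2 and 3. The intervals cover counting error only.

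**Figure D1:**
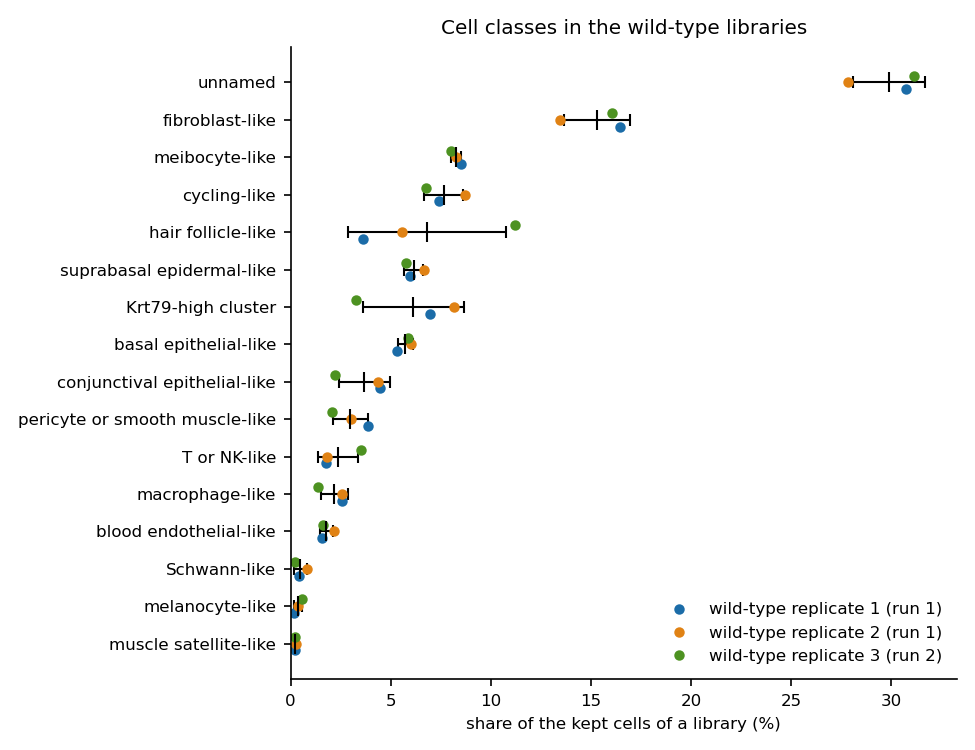
Share of cells (percent, x axis) in each rebuilt cell class (y axis), with 1 point per wild-type library and the bar at the mean ± SD of 3 libraries. Meibocyte-like cells held 8.24 ± 0.25% and the hair-follicle-like share ran from 3.60% to 11.2%.

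The first comparison set meibocyte-like against basal-epithelial-like cells and asked which genes separate the 2 classes. Whether the basal-epithelial-like cluster, high in Lgr5, Lhx2 and Cd34, holds the basal cells of the gland was not tested. Lists of lipid synthesis and esterification genes were called higher in meibocyte-like cells. Of these, cholesterol synthesis and ester assembly lost their calls with an estimated correlation (camera adjusted p = 0.0551 and 0.161). Awat2 was 233-fold higher (counting interval 41.7 to 9202) in meibocyte-like cells (45.5 ± 19.7 CPM, n = 3). Far2 (ENSMUSG00000030303, chromosome 6, 148047259 to 148182758), which reduces fatty acyl-CoA to the fatty alcohols of wax esters, reached 88.6 ± 1.61 CPM against 0 UMIs in basal-epithelial-like cells, so it was at least 176-fold higher. Basal-epithelial-like cells held more transcript of the Hedgehog target genes Ptch1 and Gli1, the stem cell gene Lgr5 and the immediate early gene Fos.

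Sterol and glyceride acyltransferases were also higher in meibocyte-like cells, with n = 3 libraries for each value. The cholesteryl ester gene, on chromosome 1 (156424525 to 156474331), was Soat1 (249 ± 35.7 and 8.84 ± 1.11 CPM, log2FC 5.29 ± 0.25), and the triglyceride gene was Dgat2 (145 ± 4.19 and 27.6 ± 6.47 CPM, log2FC 2.78 ± 0.15). These are class averages, and in the keratin-high meibocyte-like subcluster described below mean Soat1 and Dgat2 lay near the basal-epithelial-like levels. The elongases of long fatty acids were higher, with Elovl3 (167 ± 31.9 and 0.757 ± 0.673 CPM, log2FC 7.65 ± 0.29) and Elovl4 (54.3 ± 17.4 and 6.14 ± 1.90 CPM, log2FC 3.59 ± 0.26). So were the elongases Elovl6 (298 ± 179 and 22.9 ± 4.64 CPM, log2FC 4.07 ± 0.28) and Elovl1 (107 ± 25.2 and 27.9 ± 10.0 CPM, log2FC 2.40 ± 0.20). The Hedgehog target genes were lower, with Ptch1 (6.88 ± 3.41 and 65.4 ± 42.4 CPM, log2FC -2.85 ± 0.23) and Gli1 (0.463 ± 0.138 and 35.5 ± 18.2 CPM, log2FC -5.87 ± 0.45). For these genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 2.9e-10 for Awat2, 1.2e-10 for Soat1 and 1.9e-11 for Elovl3, each higher in 3 of 3 libraries.

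By fold change, the genes furthest above basal-epithelial-like cells included the hormone gene Cck (307 ± 51.1 and 0.344 ± 0.595 CPM, log2FC 9.31 ± 0.56) and the lipoprotein lipase gene Lpl (111 ± 7.34 and 0.912 ± 0.989 CPM, log2FC 7.52 ± 0.35). The thioesterase gene Acot5 was at least 128-fold higher (90.5 ± 60.5 CPM against 0 UMIs). The retinol dehydrogenase family member Sdr16c6 was 708-fold higher (counting interval 127 to 27985), and the peroxisomal thiolase gene Acaa1b was 153-fold higher (counting interval 52.1 to 740.3). In the other direction, Cxcl14 (7.14 ± 3.61 and 3067 ± 427 CPM, log2FC -8.33 ± 0.31), a chemokine gene, Krt24 (log2FC -9.12 ± 0.42) and Capns2 (log2FC -8.06 ± 0.33) were lower, and the protocadherin gene Pcdh20 was at least 849-fold lower.

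Most sterol and fatty acid synthesis genes were higher. For cholesterol synthesis, 21 of 23 measured members were higher, 0 lower and 2 not called (camera adjusted p = 5.7e-11, and adjusted p = 0.0551 with an estimated correlation). Among them was Mvd (106 ± 14.9 and 2.33 ± 0.377 CPM, log2FC 5.78 ± 0.22). Acat2 was higher at 255 ± 29.1 and 12.9 ± 4.59 CPM, and Msmo1 at 714 ± 187 and 33.7 ± 12.6 CPM. For de novo lipogenesis, 9 of 9 measured members were higher, 0 lower and 0 not called (camera adjusted p = 3.7e-05, and adjusted p = 0.0325 with an estimated correlation). Among them were Acss2 (log2FC 5.15 ± 0.28) and Me1 (194 ± 12.0 and 6.92 ± 2.94 CPM, log2FC 5.05 ± 0.23), whose enzyme supplies NADPH. The citrate carrier gene Slc25a1 (213 ± 19.2 and 18.7 ± 3.87 CPM, log2FC 3.86 ± 0.15) was higher too. Among fatty acid elongation and very long chain lipid genes, 18 of 25 measured members were higher, 4 lower and 3 not called (camera adjusted p = 0.000211, and adjusted p = 0.0352 with an estimated correlation). The acyl-CoA synthetase genes Acsl4 (log2FC 4.23 ± 0.19) and Acsl5 (log2FC 4.19 ± 0.13) were among the higher. For wax ester, sterol ester and glyceride assembly, 7 of 11 measured members were higher, 0 lower and 4 not called (camera adjusted p = 0.0136, and adjusted p = 0.161 with an estimated correlation). Awat2, Far2, Soat1 and Dgat2 were among the higher.

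Lipid storage and oxidation genes were higher too. Among lipid droplet genes, 7 of 10 measured members were higher, 2 lower and 1 not called (camera adjusted p = 0.0294, and adjusted p = 0.142 with an estimated correlation). The monoglyceride lipase gene Mgll (233 ± 29.6 and 22.2 ± 4.21 CPM, log2FC 3.70 ± 0.22) was higher, as were Fitm2 (log2FC 3.28 ± 0.23) and Hilpda (log2FC 2.80 ± 0.17). In mitochondrial fatty acid oxidation, 14 of 16 measured members were higher, 0 lower and 2 not called (camera adjusted p = 5.4e-07, and adjusted p = 0.0256 with an estimated correlation). Among them were Hadh (475 ± 33.0 and 80.4 ± 9.44 CPM, log2FC 2.94 ± 0.11), Decr1 (log2FC 2.96 ± 0.17) and Hadha (log2FC 2.26 ± 0.12). Peroxisome genes were higher in most cases, and 18 of 27 measured members were higher, 1 lower and 8 not called (camera adjusted p = 1.7e-06, and adjusted p = 0.0610 with an estimated correlation). The carnitine acetyltransferase gene was higher, with Crat (89.8 ± 12.9 and 2.13 ± 1.34 CPM, log2FC 5.59 ± 0.23). Other examples were Scp2 (967 ± 96.6 and 182 ± 13.4 CPM, log2FC 2.78 ± 0.09) and Hsd17b4 (log2FC 2.98 ± 0.16). Within PPAR targets, 7 of 11 measured members were higher, 2 lower and 2 not called (camera adjusted p = 0.0285, and adjusted p = 0.176 with an estimated correlation). The higher included Pdk4 (147 ± 37.8 and 1.62 ± 0.565 CPM, log2FC 6.78 ± 0.28), and the list call was lost with doublets kept (adjusted p = 0.0577).

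The Hedgehog, adhesion, Notch and niche growth factor lists were called lower in meibocyte-like cells, and each of these calls was lost with an estimated correlation. For Hedgehog, 0 of 10 measured members were higher, 9 lower and 1 not called (camera adjusted p = 0.000182, and adjusted p = 0.0610 with an estimated correlation). Among them was Gli2 (log2FC -6.18 ± 0.54) beside Ptch1 and Gli1. For basement membrane adhesion, 0 of 13 measured members were higher, 8 lower and 5 not called (camera adjusted p = 0.000211, and adjusted p = 0.0938 with an estimated correlation). The integrin gene Itga2 (log2FC -6.87 ± 0.36) and the laminin genes Lama5 (log2FC -3.97 ± 0.27) and Lamb3 (9.03 ± 2.75 and 136 ± 33.8 CPM, log2FC -3.51 ± 0.13) were lower. So was Col7a1 (log2FC -3.42 ± 0.25), the collagen gene of anchoring fibrils. In the Notch list, 0 of 13 measured members were higher, 6 lower and 7 not called (camera adjusted p = 0.00654, and adjusted p = 0.212 with an estimated correlation). Among them were Maml2 (log2FC -2.87 ± 0.32) and Lfng (log2FC -2.51 ± 0.35). For niche growth factors, 2 of 19 measured members were higher, 9 lower and 8 not called (camera adjusted p = 0.0206, and adjusted p = 0.145 with an estimated correlation). The lower included Dkk3 (2.51 ± 0.651 and 153 ± 19.4 CPM, log2FC -5.64 ± 0.25), Bmp2 (log2FC -4.66 ± 0.43) and Sfrp1 (log2FC -2.96 ± 0.13). This call was lost without replicate 1 (adjusted p = 0.0544) and without a low-count filter (0.0745).

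For pilosebaceous progenitor genes, 2 of 13 measured members were higher, 9 lower and 2 not called (camera adjusted p = 0.00297, and adjusted p = 0.142 with an estimated correlation). The lower included Lhx2 (0.946 ± 0.730 and 247 ± 13.4 CPM, log2FC -7.37 ± 0.30), Lgr5 (0.582 ± 0.525 and 142 ± 55.0 CPM, log2FC -7.27 ± 0.24) and Cd34 (log2FC -5.34 ± 0.25), and the list call was lost with doublets kept (adjusted p = 0.0562), with a plain neighbour graph (0.0523) and under another random split of the genes (0.0722). Immediate early and dissociation stress genes were lower in meibocyte-like cells, and 0 of 17 measured members were higher, 12 lower and 5 not called (camera adjusted p = 0.000211, and adjusted p = 0.348 with an estimated correlation). Among them were Hspb1 (58.6 ± 25.1 and 2632 ± 406 CPM, log2FC -5.03 ± 0.34), Fos (294 ± 99.3 and 4274 ± 1216 CPM, log2FC -3.46 ± 0.31) and Socs3 (log2FC -4.04 ± 0.24). The camera call was not reached for cornified envelope and keratinization (adjusted p = 0.325), DNA replication and mitosis (0.401), inflammatory cytokines and chemokines (0.223), interferon response (0.0866), lysosome (0.0893), retinoid handling (0.649) or steroid hormone receptors and enzymes (0.0716). Cells of the cycling clusters were outside both classes, so the DNA replication list was read only in the remaining cells. Several of the lists without a call were called under other settings. The inflammatory list was called lower under 6 (0.000194 to 0.00225), the interferon list lower under 6 (0.0263 to 0.0470) and the steroid list higher under 10 (0.00328 to 0.0486). The lysosome list was called lower without replicate 3 (0.0316) and retinoid handling lower with at most 10% mitochondrial UMIs (0.0468). Counts adjusted over the list alone were the same for all 14 lists called here.

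Across 5920 tested genes, edgeR called 1049 higher and 1308 lower, and 2299 of these 2357 genes moved the same way in all 3 libraries. The basal-epithelial-like class was a single cluster. Under 6 other settings the class held 13.2 to 17.9% of cells and 652 to 688 genes were higher, and with at least 1000 UMIs per cell 562 of the 1049 genes were still higher. Cells were grouped by genes kept apart from the tested genes but correlated with them. The fit took 12 sums of 4 epithelial classes with the library as a block. The p values therefore measure only how class differences varied among these pooled libraries, over the 4 classes together.

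**Figure D2:**
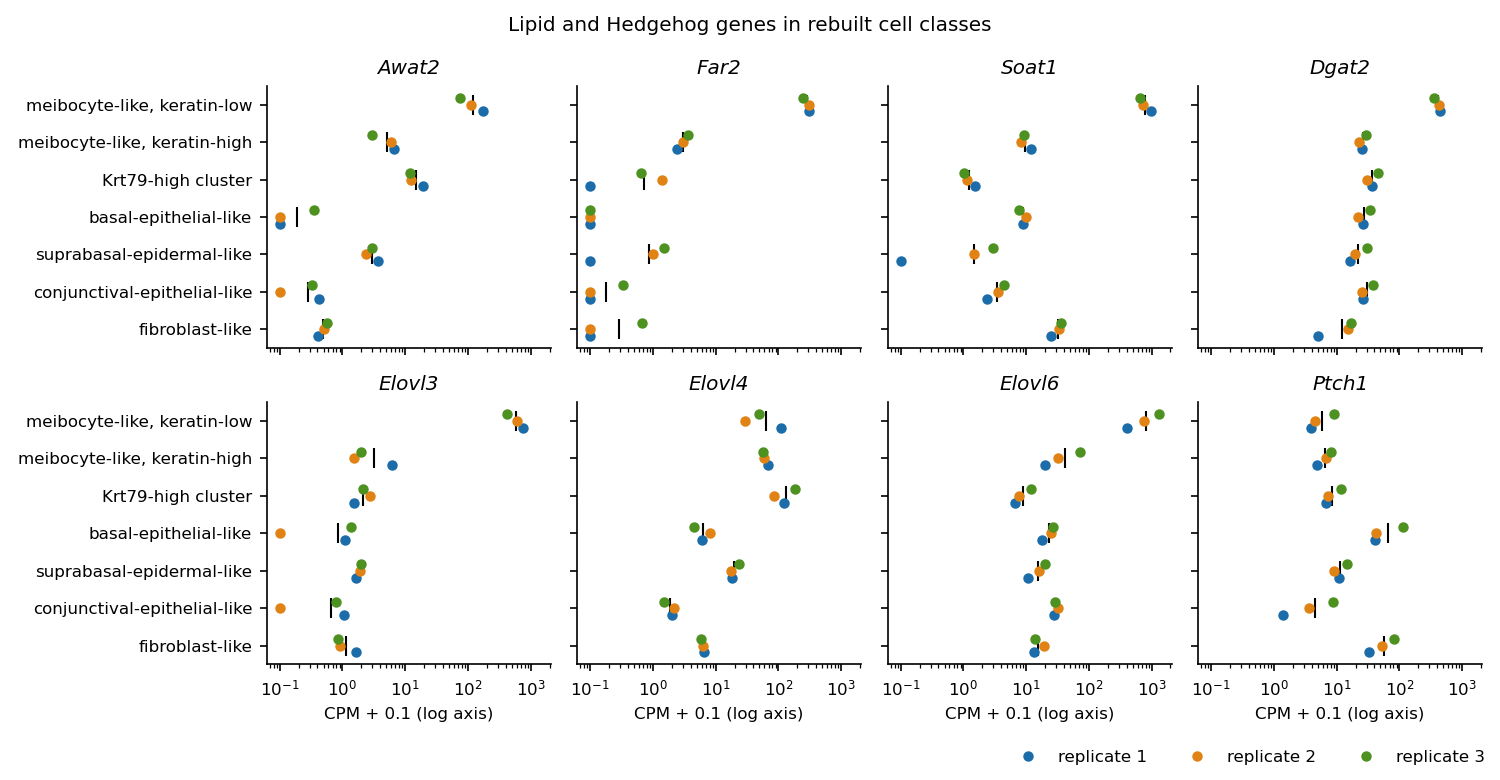
Levels of Awat2, Far2, Soat1, Dgat2, Elovl3, Elovl4, Elovl6 and Ptch1 (CPM + 0.1, log axis) in 7 rebuilt classes, with 1 point per wild-type library and the bar at the mean of 3 libraries. Awat2 reached 119.9 ± 48.1 CPM in keratin-low and 5.06 ± 1.95 CPM in keratin-high meibocyte-like cells.

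**Figure D3:**
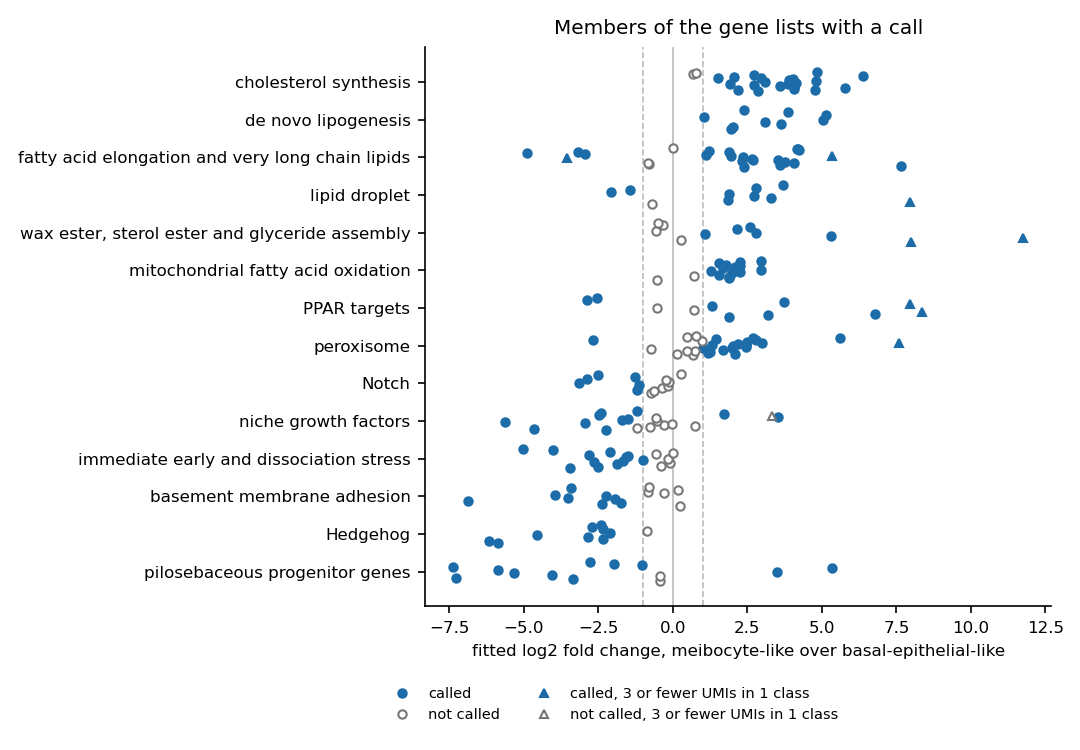
Fitted log2 fold change of each tested member (points) of the gene lists with a call, meibocyte-like over basal-epithelial-like cells, with filled points for called genes and triangles for genes with 3 or fewer UMIs in 1 class, whose fitted value depends on the prior count. In cholesterol synthesis 21 of 23 members were higher, and in Hedgehog 9 of 10 were lower.

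The next comparison set 2 meibocyte-like subclusters against each other and asked which genes separate keratin-low from keratin-high meibocyte-like cells. The subclusters with at least 20 cells in every library were ranked by summed Krt5 and Krt14, keratins of basal cells, over the libraries pooled. These reached 3185, 2766 and 1806 CPM in the keratin-low and 6612, 5740 and 3726 CPM in the keratin-high subcluster of replicates 1, 2 and 3. In replicate 2 another ranked subcluster held 5762 CPM, and the smallest subcluster, left out with 16, 9 and 22 cells, held 6408, 6327 and 5478 CPM. Median depth was 24516.5, 30818.5 and 29862 UMIs in keratin-low and 12818, 16532 and 18745.5 UMIs in keratin-high cells of the same replicates. CPM are relative to that depth, so the lower keratin CPM need not mean fewer keratin transcripts per cell. Keratin-low cells held more transcript of the wax ester genes Awat2 (119.9 ± 48.1 and 5.06 ± 1.95 CPM, log2FC 4.61 ± 0.18) and Far2 (289 ± 35.1 and 2.92 ± 0.592 CPM, log2FC 6.48 ± 0.18) (n = 3 libraries). The cholesteryl ester gene Soat1 was higher as well (792 ± 168 and 9.66 ± 1.88 CPM, log2FC 6.37 ± 0.20). Keratin-high cells held more transcript of the inflammatory, niche growth factor and adhesion lists, but these calls were lost with an estimated correlation.

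Among the other fixed genes, Dgat2 (409 ± 49.7 and 25.8 ± 3.41 CPM, log2FC 3.98 ± 0.16) and Elovl1 (log2FC 3.40 ± 0.16) were higher in keratin-low cells. The elongase genes Elovl3 (595 ± 167 and 3.13 ± 2.59 CPM, log2FC 7.64 ± 0.20) and Elovl6 (820.2 ± 444 and 41.4 ± 27.1 CPM, log2FC 4.31 ± 0.14) were higher there too. Elovl4, an elongase of very long chain fatty acids, showed no called difference (62.8 ± 42.2 and 61.4 ± 5.94 CPM, log2FC -0.016 ± 0.21), and its sign flipped under RLE scaling (0.0029). Ptch1 was not called either (log2FC -0.063 ± 0.38). From edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 4.5e-16 for Awat2, 5.8e-19 for Elovl3, 0.959 for Elovl4 and 0.897 for Ptch1, with Awat2 and Elovl3 higher in 3 of 3 libraries.

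Large differences in favour of keratin-low cells were those of Crat (285 ± 10.6 and 1.83 ± 2.35 CPM, log2FC 6.77 ± 0.25) and Fabp5 (7459 ± 2164 and 93.1 ± 9.71 CPM, log2FC 6.26 ± 0.17), a fatty acid binding protein gene. The keratin gene Krt23 (236 ± 147 and 3.75 ± 2.68 CPM, log2FC 6.00 ± 0.22) was higher as well. In favour of keratin-high cells they were those of the protease gene Prss23 (log2FC -5.60 ± 0.30), the actin regulator gene Cald1 (4.61 ± 0.700 and 191 ± 40.5 CPM, log2FC -5.30 ± 0.23) and the chemokine gene Cxcl2 (8.65 ± 5.99 and 337 ± 81.3 CPM, log2FC -5.12 ± 0.49). The aldehyde dehydrogenase gene was lower, with Aldh3a1 (9.98 ± 5.33 and 341 ± 111 CPM, log2FC -4.75 ± 0.21). Lower as well were the interferon-induced gene Ifitm3 (38.8 ± 10.4 and 946 ± 296 CPM, log2FC -4.33 ± 0.17) and the matricellular gene Thbs1 (65.6 ± 61.0 and 1374 ± 643 CPM, log2FC -4.40 ± 0.18).

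Lipid lists were higher in keratin-low cells. For cholesterol synthesis, 22 of 23 measured members were higher, 0 lower and 1 not called (camera adjusted p = 1.0e-16, and adjusted p = 0.0414 with an estimated correlation). Among them were Mvd (373 ± 94.3 and 3.88 ± 1.46 CPM, log2FC 6.45 ± 0.19) and Acat2 (log2FC 5.29 ± 0.13). In de novo lipogenesis, 8 of 9 measured members were higher, 0 lower and 1 not called (camera adjusted p = 4.0e-07, and adjusted p = 0.0610 with an estimated correlation). Among them were Acss2 (log2FC 5.05 ± 0.14) and Mid1ip1 (466 ± 84.3 and 15.2 ± 2.93 CPM, log2FC 4.91 ± 0.20), a regulator of acetyl-CoA carboxylase. For elongation and very long chain lipids, 12 of 19 measured members were higher, 0 lower and 7 not called (camera adjusted p = 1.4e-07, and adjusted p = 0.0256 with an estimated correlation). Among them were the ceramide synthase gene Cers4 (769 ± 168 and 23.9 ± 4.96 CPM, log2FC 4.92 ± 0.14) and Hacd2 (1111 ± 148 and 52.4 ± 6.73 CPM, log2FC 4.40 ± 0.12). Peroxisome genes followed, and 23 of 26 measured members were higher, 0 lower and 3 not called (camera adjusted p = 3.7e-12, and adjusted p = 0.0256 with an estimated correlation). Among them were Pex16 (221 ± 51.5 and 11.8 ± 3.65 CPM, log2FC 4.28 ± 0.15) and Abcd3 (log2FC 2.87 ± 0.11). For wax ester, sterol ester and glyceride assembly, 8 of 11 measured members were higher, 2 lower and 1 not called (camera adjusted p = 0.00170, and adjusted p = 0.161 with an estimated correlation).

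In the lipid droplet list, 7 of 9 measured members were higher, 0 lower and 2 not called (camera adjusted p = 0.000702, and adjusted p = 0.134 with an estimated correlation). Among them were Mgll (log2FC 3.93 ± 0.16) and Cidec (log2FC 2.16 ± 0.38). Mitochondrial fatty acid oxidation moved likewise, and 8 of 16 measured members were higher, 0 lower and 8 not called (camera adjusted p = 6.9e-06, and adjusted p = 0.0684 with an estimated correlation). Among them were Hadh (log2FC 2.34 ± 0.09) and Cpt2 (log2FC 2.34 ± 0.25). Among lysosome genes, 7 of 19 measured members were higher, 2 lower and 10 not called (camera adjusted p = 0.00610, and adjusted p = 0.134 with an estimated correlation). Among them were Atp6v0d1 (log2FC 2.17 ± 0.15) and Psap (log2FC 1.20 ± 0.09), and the call was lost under another random split of the genes (adjusted p = 0.208).

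The inflammatory, niche growth factor, adhesion, DNA replication and pilosebaceous lists were called lower in keratin-low cells, and each of these calls was lost with an estimated correlation. All inflammatory genes measured were lower, and 0 of 10 measured members were higher, 10 lower and 0 not called (camera adjusted p = 0.00273, and adjusted p = 0.105 with an estimated correlation). Among them were Cxcl1 (96.9 ± 43.8 and 1429 ± 618 CPM, log2FC -3.84 ± 0.23) and Cxcl16, which was 144-fold lower (counting interval 25.6 to 5722). For niche growth factors, 0 of 15 measured members were higher, 10 lower and 5 not called (camera adjusted p = 0.000211, and adjusted p = 0.0938 with an estimated correlation). Among them were Nrg1 (log2FC -3.64 ± 0.34), the epidermal growth factor receptor ligand Areg (log2FC -3.26 ± 0.25) and Tgfb2 (log2FC -4.91 ± 0.35). Basement membrane adhesion was lower, and 0 of 10 measured members were higher, 8 lower and 2 not called (camera adjusted p = 0.00237, and adjusted p = 0.134 with an estimated correlation). Among them were Itgb4 (log2FC -3.17 ± 0.28) and Lama3 (log2FC -2.84 ± 0.28). For DNA replication and mitosis, 0 of 15 measured members were higher, 9 lower and 6 not called (camera adjusted p = 0.0137, and adjusted p = 0.275 with an estimated correlation). Among them were the helicase genes Mcm5 (log2FC -2.65 ± 0.41) and Mcm6 (log2FC -2.21 ± 0.24). Cells of the cycling clusters and of a subcluster led by Cenpa and Cdca3 stood apart, so this result covers the remaining cells. Pilosebaceous progenitor genes were lower, and 0 of 7 measured members were higher, 5 lower and 2 not called (camera adjusted p = 0.00803, and adjusted p = 0.0938 with an estimated correlation). Among them were Plet1 (67.0 ± 24.4 and 1040.4 ± 213 CPM, log2FC -3.82 ± 0.16) and Sox9 (112 ± 45.7 and 506 ± 30.3 CPM, log2FC -2.11 ± 0.17). Counts adjusted over the list alone were the same for all 13 lists called.

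Of 4702 genes tested, edgeR called 763 higher and 814 lower in keratin-low cells. The subclusters were defined within the same cells by genes correlated with the tested ones, and the keratin-low subcluster held 54, 38 and 177 cells in replicates 1, 2 and 3.

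The Krt79-high cluster was compared with meibocyte-like cells in place of a planned comparison with ductal-epithelial-like cells, a choice made after the clusters were seen. Meibocyte-like cells held more transcript of the acyltransferase genes Awat2, Soat1 and Dgat2. The Krt79-high cluster held more of the genes of the cornified layer. Awat2 was called higher in meibocyte-like cells (45.5 ± 19.7 and 14.6 ± 4.11 CPM, log2FC 1.61 ± 0.16, n = 3). So were Soat1 (249 ± 35.7 and 1.13 ± 0.273 CPM, log2FC 7.80 ± 0.26) and Far2 (88.6 ± 1.61 and 0.620 ± 0.658 CPM, log2FC 7.12 ± 0.33). These are averages over the meibocyte-like class. In its keratin-high subcluster (607 of the 1481 cells), Awat2 reached only 6.59, 5.74 and 2.86 CPM in replicates 1, 2 and 3. Both Awat2 and mean Dgat2 of that subcluster lay below the Krt79-high cluster. The protease inhibitor gene Cst6 (85.0 ± 66.8 and 46452 ± 17053 CPM, log2FC -9.26 ± 0.38) was lower in meibocyte-like cells.

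Further fixed genes higher in meibocyte-like cells were Dgat2 (145 ± 4.19 and 37.2 ± 7.13 CPM, log2FC 2.00 ± 0.12), Elovl3 (167 ± 31.9 and 2.02 ± 0.591 CPM, log2FC 6.32 ± 0.21) and Elovl6 (298 ± 179 and 8.76 ± 2.90 CPM, log2FC 5.03 ± 0.26). Elovl1 (1.30 ± 0.16) lost its call under another random split of the genes (0.81). Elovl4 was lower in meibocyte-like cells (54.3 ± 17.4 and 131 ± 51.3 CPM, log2FC -1.26 ± 0.22), but the call was lost without replicate 3 (-0.77) and at Leiden resolution 0.5 (-0.59), where the cluster also took the suprabasal-epidermal-like name. Ptch1 (-0.29) and Gli1 (0.26) were not called. Applying edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 1.7e-07 for Awat2, 4.4e-13 for Soat1 and 3.1e-12 for Cst6, each with 1 direction in 3 of 3 libraries. The ceramide synthase gene Cers4 (275 ± 30.7 and 3.64 ± 1.65 CPM, log2FC 6.16 ± 0.21) and Acaa1b (log2FC 5.27 ± 0.27) were higher. Lower were the defensin gene Defb6 (4.71 ± 2.29 and 2475 ± 808 CPM, log2FC -9.09 ± 0.47) and the lipoxygenase gene Alox12e (2.24 ± 0.0778 and 487 ± 43.3 CPM, log2FC -7.81 ± 0.42). The desmosomal gene Dsg1a (log2FC -7.89 ± 0.51) and the gasdermin gene Gsdma (log2FC -7.56 ± 0.27) were lower too.

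For cornified envelope and keratinization, 0 of 17 measured members were higher, 16 lower and 1 not called (camera adjusted p = 4.7e-10, and adjusted p = 0.0180 with an estimated correlation). The envelope gene Cnfn was at least 121-fold lower and the kallikrein gene Klk5 at least 108-fold lower. The filaggrin gene Flg was at least 477-fold lower, but in 1 of 3 libraries, and without replicate 2 its call was lost (-0.069). Inflammatory genes were lower in meibocyte-like cells, and 0 of 18 measured members were higher, 15 lower and 3 not called (camera adjusted p = 8.6e-05, and adjusted p = 0.0718 with an estimated correlation). Examples were Il18 (log2FC -6.28 ± 0.60), Il1a (log2FC -5.37 ± 0.80) and the antagonist gene Il1rn (3.24 ± 0.896 and 67.2 ± 3.66 CPM, log2FC -4.10 ± 0.35). Within the interferon response, 0 of 10 measured members were higher, 6 lower and 4 not called (camera adjusted p = 0.0177, and adjusted p = 0.317 with an estimated correlation). Among them were Irf1 (log2FC -2.12 ± 0.21) and Ifi27l2a (log2FC -2.14 ± 0.21). In immediate early and dissociation stress, 0 of 17 measured members were higher, 9 lower and 8 not called (camera adjusted p = 0.00257, and adjusted p = 0.412 with an estimated correlation). Among them were Hspb1 (58.6 ± 25.1 and 1393 ± 355 CPM, log2FC -4.46 ± 0.32) and Dusp1 (log2FC -2.80 ± 0.26). For pilosebaceous progenitor genes, 2 of 13 measured members were higher, 5 lower and 6 not called (camera adjusted p = 0.0161, and adjusted p = 0.156 with an estimated correlation). The lower included Prdm1 (0.615 ± 0.377 and 30.2 ± 8.42 CPM, log2FC -5.42 ± 0.34), Lrig1 (7.94 ± 3.50 and 36.3 ± 12.7 CPM, log2FC -2.19 ± 0.17) and Nfatc1 (log2FC -2.01 ± 0.21), and the list call was lost with doublets kept (adjusted p = 0.0849) and under another random split of the genes (0.152). For niche growth factors, 1 of 19 measured members were higher, 5 lower and 13 not called (camera adjusted p = 0.0312, and adjusted p = 0.142 with an estimated correlation). Its lower genes included the epidermal growth factor receptor ligands Ereg (log2FC -4.92 ± 0.55) and Hbegf (log2FC -1.89 ± 0.26), and the call was lost under 5 settings (adjusted p = 0.0560 to 0.418), among them without replicate 2 (0.0851).

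The lists higher in meibocyte-like cells were again those of lipid metabolism. In cholesterol synthesis, 21 of 23 measured members were higher, 0 lower and 2 not called (camera adjusted p = 3.4e-17, and adjusted p = 0.0256 with an estimated correlation). Among them were Idi1 (1064 ± 257 and 57.2 ± 17.6 CPM, log2FC 4.27 ± 0.15), Acat2 (log2FC 4.65 ± 0.17) and Lss (log2FC 4.29 ± 0.22). De novo lipogenesis was higher throughout, and 9 of 9 measured members were higher, 0 lower and 0 not called (camera adjusted p = 1.4e-07, and adjusted p = 0.0180 with an estimated correlation). Among them were the fatty acid synthase gene Fasn (198 ± 93.9 and 21.7 ± 7.75 CPM, log2FC 3.18 ± 0.12) and Acss2 (log2FC 4.94 ± 0.26). Among peroxisome genes, 17 of 27 measured members were higher, 1 lower and 9 not called (camera adjusted p = 1.1e-09, and adjusted p = 0.0256 with an estimated correlation). Among them were the catalase gene Cat (114 ± 14.3 and 18.5 ± 3.21 CPM, log2FC 2.64 ± 0.15) and Crat (log2FC 5.18 ± 0.19). For mitochondrial fatty acid oxidation, 7 of 16 measured members were higher, 1 lower and 8 not called (camera adjusted p = 1.7e-06, and adjusted p = 0.0180 with an estimated correlation). Among them were Decr1 (log2FC 2.06 ± 0.14) and Eci1 (log2FC 1.82 ± 0.12). For elongation and very long chain lipids, 11 of 25 measured members were higher, 4 lower and 10 not called (camera adjusted p = 0.000211, and adjusted p = 0.0610 with an estimated correlation). The reductase gene Hsd17b12 (log2FC 3.59 ± 0.13) was among the higher. For lipid droplet genes, 5 of 10 measured members were higher, 0 lower and 5 not called (camera adjusted p = 0.00365, and adjusted p = 0.134 with an estimated correlation). Among them were Mgll (log2FC 2.15 ± 0.26) and Bscl2 (log2FC 1.54 ± 0.13). The assembly list of wax and sterol esters was called too, and 6 of 11 measured members were higher, 0 lower and 5 not called (camera adjusted p = 0.00257, and adjusted p = 0.0938 with an estimated correlation). The acyltransferase gene Gpam (log2FC 2.29 ± 0.26) was among the higher. Counts adjusted over the list alone were the same for all 13 lists called. Of 6094 genes tested, edgeR called 441 higher and 880 lower in meibocyte-like cells. Under another random split of the genes 695 of 6389 tested genes were higher. The basement membrane adhesion list (adjusted p = 0.0502) was called lower under 5 other settings (0.00171 to 0.0475). The Krt79-high cluster is a single unnamed cluster whose best class was suprabasal-epidermal.

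The Krt79-high cluster was also compared with basal-epithelial-like cells, again as a comparison added after the clusters were seen. The Krt79-high cluster held more Awat2, Elovl4 and cornified-layer transcript, and less Hedgehog and adhesion transcript, where both list calls were lost with an estimated correlation. Awat2 was 84.7-fold higher (counting interval 15.0 to 3365) in the Krt79-high cluster (14.6 ± 4.11 and 0.0859 ± 0.149 CPM, n = 3), and Elovl4 (131 ± 51.3 and 6.14 ± 1.90 CPM, log2FC 5.00 ± 0.35) was higher as well. Soat1 was lower (1.13 ± 0.273 and 8.84 ± 1.11 CPM, log2FC -2.51 ± 0.45), as were Ptch1 (log2FC -2.55 ± 0.23) and Gli1 (log2FC -6.11 ± 0.54), although Ptch1 lost its call under another random split of the genes (-0.94). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 9.3e-09 for Awat2, 3.6e-09 for Elovl4 and 0.000158 for Soat1, each with the same direction in 3 of 3 libraries. Dgat2 (0.80), Elovl3 (1.34) and Elovl6 (-0.93) were not called. Under 6 other settings, all with a larger basal-epithelial-like class, Dgat2 (1.63 to 2.17) and Elovl3 (1.56 to 1.92) were called higher. Elovl6 was called lower under 6 settings (-1.01 to -1.36). Elovl1 was called at 1.12 but lost its call under 8 (0.56 to 0.88).

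The genes furthest above basal-epithelial-like cells included the transcription factor gene Ehf (382 ± 47.3 and 2.29 ± 1.20 CPM, log2FC 8.05 ± 0.24) and the cornified envelope precursor gene Sprr1a (4751 ± 2212 and 28.6 ± 10.3 CPM, log2FC 7.60 ± 0.28). Higher too were Clca3a2 (246 ± 32.0 and 2.27 ± 1.96 CPM, log2FC 7.45 ± 0.32) and Cst6 (46452 ± 17053 and 106 ± 54.2 CPM, log2FC 9.23 ± 0.38). The kallikrein gene Klk6 was at least 112-fold higher. The T-box gene Tbx1 (0.549 ± 0.475 and 187 ± 27.3 CPM, log2FC -7.80 ± 0.33), the neurotrophin gene Bdnf (log2FC -8.11 ± 0.35), Aspn (log2FC -7.08 ± 0.42) and Lgr5 (log2FC -6.97 ± 0.30) were among the lower genes.

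For cornified envelope and keratinization, 15 of 17 measured members were higher, 1 lower and 1 not called (camera adjusted p = 7.7e-06, and adjusted p = 0.0256 with an estimated correlation). The kallikrein gene was higher, with Klk7 (263 ± 151 and 1.94 ± 2.33 CPM, log2FC 7.35 ± 0.51), and Cnfn was at least 25.7-fold higher. In elongation and very long chain lipids, of 25 measured members 11 were higher and 4 lower, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.0177, and adjusted p = 0.156 with an estimated correlation). Among them were Acsl4 (172 ± 24.3 and 12.8 ± 4.20 CPM, log2FC 4.20 ± 0.18) and Elovl7 (log2FC 3.50 ± 0.27). For mitochondrial fatty acid oxidation, 6 of 16 measured members were higher, 0 lower and 10 not called (camera adjusted p = 0.000102, and adjusted p = 0.0256 with an estimated correlation). Among them were Etfdh (log2FC 1.88 ± 0.12) and Hadh (log2FC 1.37 ± 0.10), and Hadh lost its call when unnamed clusters took their best class (0.997). Hedgehog genes were lower, and 0 of 10 measured members were higher, 8 lower and 2 not called (camera adjusted p = 0.000211, and adjusted p = 0.0938 with an estimated correlation). Among them was Gli2 (log2FC -3.56 ± 0.50), and the list call was lost with at most 10% mitochondrial UMIs (adjusted p = 0.0573). Basement membrane adhesion genes were lower, and 0 of 13 measured members were higher, 8 lower and 5 not called (camera adjusted p = 8.6e-05, and adjusted p = 0.142 with an estimated correlation). Among them were Itga2 (log2FC -4.37 ± 0.33) and Itga3 (log2FC -2.28 ± 0.23). In immediate early and dissociation stress, 0 of 17 measured members were higher, 7 lower and 10 not called (camera adjusted p = 0.00657, and adjusted p = 0.449 with an estimated correlation). Among them were Fos (715 ± 75.6 and 4274 ± 1216 CPM, log2FC -2.22 ± 0.28) and Fosb (log2FC -1.46 ± 0.31). The list call was lost under 7 settings, from adjusted p = 0.0606 without replicate 2 to 0.837 under another random split of the genes, and that split also ended the calls of Fos (-0.61) and Fosb (-0.96). Cholesterol synthesis was not called (5 of 23 higher and 1 lower, camera adjusted p = 0.123), but was called higher under 7 settings (adjusted p = 4.2e-06 to 0.0210). PPAR targets missed the call (adjusted p = 0.0622) and were called higher under 12 settings (0.00850 to 0.0482). Lists further from a call changed too: de novo lipogenesis (adjusted p = 0.417) was called higher under 5 settings (0.0160 to 0.0401), the steroid list (0.267) higher under 4 (0.0103 to 0.0334) and niche growth factors (0.214) lower under 5 (0.00135 to 0.0144). For the other 5 called lists the counts adjusted over the list alone were the same, and of 6094 genes tested edgeR called 908 higher and 924 lower. Both the Krt79-high and the basal-epithelial-like class were single clusters, and the latter grew in most other groupings. Genes higher were then 541 with at least 1000 UMIs, 562 with at most 10% mitochondrial UMIs and 584 with a plain neighbour graph. Giving unnamed clusters their best class left 534. In these settings 43.4 to 46.6% of the 908 genes that were tested again stayed higher.

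The last comparison set fibroblast-like cells against the mean of the 4 epithelial classes, meibocyte-, basal-, suprabasal- and conjunctival-epithelial-like cells, and asked which genes separate fibroblast-like cells from that mean. Fibroblast-like cells held more Hedgehog response transcript than the epithelial mean, with Ptch1 (56.0 ± 25.3 and 22.0 ± 13.0 CPM, log2FC 1.86 ± 0.15) (n = 3 libraries). The Hedgehog effector gene Gli1 (15.8 ± 1.66 and 9.50 ± 4.76 CPM, log2FC 2.78 ± 0.31) was higher too. Basal-epithelial-like cells, 1 of the 4 classes, held more of both on average than fibroblast-like cells, with Ptch1 at 65.4 ± 42.4 CPM and Gli1 at 35.5 ± 18.2 CPM. Fibroblast-like cells also held more of the secreted signals Dkk2, Igf1 and Fgf7. The epithelial classes held more transcript of barrier, adhesion, cell division and sterol synthesis genes, and of these lists only the cornified envelope kept its call with an estimated correlation.

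Awat2 was lower in fibroblast-like cells (0.393 ± 0.0809 and 12.2 ± 5.04 CPM, log2FC -2.02 ± 0.66), but the call was lost under 6 settings (-1.21 to -1.85) and reversed when unnamed clusters took their best class (0.68). Dgat2 (12.3 ± 6.43 and 56.0 ± 6.05 CPM, log2FC -2.07 ± 0.19) and Elovl6 (15.5 ± 3.17 and 91.4 ± 46.8 CPM, log2FC -1.83 ± 0.26) were lower. Elovl3 (1.03 ± 0.436 and 42.4 ± 7.96 CPM, log2FC -2.27 ± 0.39) was lower with a call lost without replicate 3 (-1.60), and Elovl4 (log2FC -1.08 ± 0.22) lost its call under 6 settings (-0.40 to -0.90). Soat1 was called higher on the mean of logs (1.22 ± 0.19), while its mean CPM was lower in fibroblast-like cells (31.5 ± 6.21 and 65.7 ± 8.40 CPM) and the meibocyte-like level of 249 ± 35.7 CPM entered that mean. Its call was lost with doublets kept (0.61) and at Leiden resolution 0.5 (0.38). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, adjusted p was 7.2e-09 for Ptch1 and 0.0160 for Awat2, each with 1 direction in 3 of 3 libraries.

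The genes well above the epithelial mean included the dipeptidase gene Dpep1 (422 ± 59.6 and 0.425 ± 0.347 CPM, log2FC 10.64 ± 0.18) and the complement gene Cfb (344 ± 28.6 and 0.240 ± 0.0453 CPM, log2FC 10.52 ± 0.18). Higher too were Cpz (log2FC 10.49 ± 0.23) and the superoxide dismutase gene Sod3 (log2FC 10.29 ± 0.25), and Wnt2 was 1972-fold higher (counting interval 674 to 9571). Well below it were the epithelial adhesion gene Epcam (4.85 ± 2.13 and 422 ± 98.5 CPM, log2FC -6.38 ± 0.23) and the aquaporin gene Aqp3 (5.24 ± 1.98 and 891 ± 222 CPM, log2FC -6.21 ± 0.29). The adhesion gene Fermt1 (log2FC -6.41 ± 0.19) and the serpin gene Serpinb5 (log2FC -6.59 ± 0.32) were lower too.

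Among Hedgehog genes, 9 of 11 measured members were higher, 0 lower and 2 not called (camera adjusted p = 0.00170, and adjusted p = 0.0938 with an estimated correlation). Among them were Hhip (42.1 ± 19.1 and 0.852 ± 0.710 CPM, log2FC 7.08 ± 0.26), Cdon (69.0 ± 18.0 and 9.66 ± 3.40 CPM, log2FC 3.05 ± 0.15) and Gli2 (log2FC 3.15 ± 0.27). For niche growth factors, 17 of 28 measured members were higher, 7 lower and 4 not called (camera adjusted p = 0.0285, and adjusted p = 0.105 with an estimated correlation). Among them were Dkk2 (312 ± 58.6 and 0.279 ± 0.197 CPM, log2FC 10.28 ± 0.26), Igf1 (566 ± 63.5 and 0.418 ± 0.459 CPM, log2FC 9.57 ± 0.22) and Fgf7 (153 ± 0.351 and 0.297 ± 0.368 CPM, log2FC 8.96 ± 0.24). In the lysosome list, 11 of 20 measured members were higher, 1 lower and 8 not called (camera adjusted p = 0.000906, and adjusted p = 0.145 with an estimated correlation). Among them were Hexa (226 ± 10.9 and 12.3 ± 2.34 CPM, log2FC 5.09 ± 0.13), Ctsb (835 ± 19.6 and 191 ± 3.24 CPM, log2FC 1.90 ± 0.07) and Lipa (log2FC 2.78 ± 0.16). For interferon response, 9 of 12 measured members were higher, 0 lower and 3 not called (camera adjusted p = 0.00704, and adjusted p = 0.314 with an estimated correlation). Among them were Ifit3 (log2FC 5.87 ± 0.42) and Bst2 (160.0 ± 51.8 and 11.5 ± 4.06 CPM, log2FC 3.37 ± 0.20).

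Lower lists began with the cornified envelope, and 0 of 16 measured members were higher, 12 lower and 4 not called (camera adjusted p = 3.2e-05, and adjusted p = 0.0256 with an estimated correlation). The protease gene Asprv1 (log2FC -6.09 ± 0.46) was among the lower. The call of the envelope gene Ivl (log2FC -5.53 ± 0.64) was lost without replicate 3 (-4.86). In basement membrane adhesion, 1 of 13 measured members were higher, 8 lower and 4 not called (camera adjusted p = 0.00138, and adjusted p = 0.134 with an estimated correlation). Among them were the basal transcription factor gene Trp63 (6.10 ± 3.39 and 184 ± 23.1 CPM, log2FC -4.92 ± 0.22), Lama3 (log2FC -4.79 ± 0.33) and Itga3 (log2FC -4.33 ± 0.26). For cholesterol synthesis, 0 of 23 measured members were higher, 15 lower and 8 not called (camera adjusted p = 0.000190, and adjusted p = 0.134 with an estimated correlation). Among them was Msmo1 (log2FC -1.75 ± 0.15). For DNA replication and mitosis, 0 of 17 measured members were higher, 10 lower and 7 not called (camera adjusted p = 0.00157, and adjusted p = 0.142 with an estimated correlation). Among them were Mcm5 (log2FC -2.78 ± 0.31) and Cdc20 (log2FC -2.07 ± 0.26). Cells of the cycling clusters were outside all classes compared, so this result covers the remaining cells. For elongation and very long chain lipids, 4 of 25 measured members were higher, 13 lower and 8 not called (camera adjusted p = 0.0130, and adjusted p = 0.142 with an estimated correlation). Among them were Elovl7 (log2FC -3.04 ± 0.33) and Hacd2 (log2FC -2.09 ± 0.12). Mitochondrial fatty acid oxidation completed the lower lists, and 0 of 16 measured members were higher, 5 lower and 11 not called (camera adjusted p = 0.000316, and adjusted p = 0.0256 with an estimated correlation). Among them were Hadh (log2FC -2.02 ± 0.11) and Acadm (log2FC -1.42 ± 0.10). Counts adjusted over the list alone were the same for all 10 lists called. Of 6454 genes tested, edgeR called 1581 higher and 1109 lower in fibroblast-like cells, and a mean over 4 unlike classes describes none of them alone.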

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

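The 2 comparisons with the Krt79-high cluster and the setting that gave unnamed clusters their best class were chosen only after the clusters were seen. Over the alternatives, named genes kept their direction and their side of the threshold in 4444 cases, lost a call in 69, gained one in 32 and reversed in 25. Fixed lists did so in 1306, 22, 88 and 33 cases, and no called list reversed. These totals include cases that could not change. For fibroblast-like cells, using only the sums of the compared classes was the same fit. Giving unnamed clusters their best class left the keratin comparison as it was. Of the reversed genes Adh1, Awat2, Slc1a3, Far2 and Egr1 were called in the reported comparisons. The other 4 lost their call, while Adh1 was called in the other direction. It was 374-fold higher in meibocyte-like than in basal-epithelial-like cells (counting interval 67.1 to 14791), with 1759 UMIs against 1, and log2 fold changes of 6.95 to 11.43 with 1 replicate left out. But it was called lower with at least 1000 UMIs, at most 10% mitochondrial UMIs and a plain neighbour graph (adjusted p = 0.000301, 5.9e-06 and 3.5e-05). With doublets kept (adjusted p = 4.3e-05) and with unnamed clusters given their best class (0.00946) it was lower by less than the log2 threshold of 1. In that last setting the meibocyte-like clusters were those of the reported grouping, while clusters of 1314, 523 and 411 cells joined the basal-epithelial-like class. Beyond this, the cause of the values that moved or reversed was not tested.

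With 1 replicate left out, genes higher and lower ran from 899 to 957 and 1282 to 1439 for meibocyte-like against basal-epithelial-like cells, 654 to 804 and 685 to 841 for keratin-low against keratin-high cells, 406 to 451 and 829 to 856 for meibocyte-like cells against the Krt79-high cluster, 767 to 870 and 859 to 941 for that cluster against basal-epithelial-like cells, and 1606 to 1674 and 1010 to 1119 for fibroblast-like cells. Shares ran from 5.59 to 5.93% (basal-epithelial-like), 14.7 to 16.3% (fibroblast-like), 5.12 to 7.55% (Krt79-high cluster), 8.11 to 8.36% (meibocyte-like) and 29.3 to 30.9% (unnamed). Log2 fold changes with a reversal ran from -0.36 to 0.19 for Elovl4 and 0.020 to 0.096 for Ptch1 in the keratin comparison, and from -0.11 to 0.62 for Gli1 between meibocyte-like cells and the Krt79-high cluster. Adjusted p of lists with a reversal ran from 0.851 to 0.936 (pilosebaceous progenitor genes, fibroblast-like cells), 0.640 to 0.936 (interferon response, keratin comparison), and, for the Krt79-high cluster against basal-epithelial-like cells, 0.442 to 0.888 (DNA replication), 0.298 to 0.981 (lysosome) and 0.581 to 0.946 (interferon response).

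The remaining values are given setting by setting. Counts named in order are genes higher in meibocyte-like than in basal-epithelial-like cells, genes higher in the Krt79-high cluster than in basal-epithelial-like cells, and lists higher in the latter comparison. With at least 1000 UMIs per cell these counts were 681, 541 and 7, and 13.6% of cells were basal-epithelial-like and 22.9% unnamed. Adh1 reversed between meibocyte-like and basal-epithelial-like cells (-1.11), Elovl4 (0.039) and Ptch1 (0.094) in the keratin comparison, pilosebaceous progenitor genes in fibroblast-like cells (adjusted p = 0.755), and lysosome (0.631) and inflammatory genes (0.766) between the Krt79-high cluster and basal-epithelial-like cells. With at most 10% mitochondrial UMIs the counts were 688, 562 and 7, with 15.3% basal-epithelial-like and 24.2% unnamed. Reversed were Adh1 (-1.07), Elovl4 (0.11), pilosebaceous genes (0.717), and, in the last comparison, DNA replication (0.814), lysosome (0.488) and inflammatory genes (0.308). With doublets kept 652 genes were higher in meibocyte-like than in basal-epithelial-like cells and 5 lists in the Krt79-high cluster, with 13.2% basal-epithelial-like, 17.1% fibroblast-like and 28.0% unnamed. Reversed were Adh1 (-0.996), Elovl4 (0.078), Far2 between the Krt79-high cluster and basal-epithelial-like cells (-0.15), pilosebaceous genes (0.695), DNA replication (0.570), lysosome (0.216) and inflammatory genes (0.570).

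With a plain neighbour graph the counts were 679, 584 and 7, with 15.1% basal-epithelial-like and 21.3% unnamed, and reversed were Adh1 (-1.09), Gli1 between meibocyte-like cells and the Krt79-high cluster (-0.016), pilosebaceous genes (0.749), lysosome (0.617) and inflammatory genes (0.811). With another random gene split 687 genes were higher in meibocyte-like than in basal-epithelial-like cells and 695 than in the Krt79-high cluster. Then 7 lists were higher in the Krt79-high cluster than in basal-epithelial-like cells, and 9 lists lower in keratin-low cells. That split gave 17.9% basal-epithelial-like, 10.2% meibocyte-like and 17.6% unnamed cells. Reversed were Elovl4 (0.44) and Slc1a3 (0.11) in the keratin comparison, Far2 (-0.053) and Egr1 (0.17) between the Krt79-high cluster and basal-epithelial-like cells, pilosebaceous genes (0.769) and inflammatory genes (1.00) in fibroblast-like cells, adhesion between meibocyte-like cells and the Krt79-high cluster (0.362), and DNA replication (0.479), lysosome (0.255) and inflammatory genes (0.292) in the last comparison. With unnamed clusters given their best class the counts were 655, 534 and 7, with 16.4% basal-epithelial-like and 24.1% fibroblast-like. Reversed were Adh1 (-0.59), Awat2 in fibroblast-like cells (0.68), pilosebaceous (0.707) and Notch genes (0.832) in fibroblast-like cells, and DNA replication (0.696) and lysosome (0.639) in the last comparison.

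At Leiden resolution 0.5 the Krt79-high cluster, there the cluster named suprabasal-epidermal-like, held 12.4%, fibroblast-like cells 17.1% and unnamed clusters 27.7% of cells. Reversed were Ptch1 in the keratin comparison (0.19), Gli1 between meibocyte-like cells and the Krt79-high cluster (-0.94) and interferon genes between that cluster and basal-epithelial-like cells (0.921). Without a low-count filter 5 lists were higher in the Krt79-high cluster than in basal-epithelial-like cells, and interferon (0.971) and retinoid genes (0.775) reversed in the keratin comparison. RLE normalization reversed Elovl4 in that comparison (0.0029), as did leaving out the replicate block (0.045). Without that block, genes higher and lower were 1048 and 1264 for meibocyte-like against basal-epithelial-like cells, and the calls of Egr1 and Ifit1 between meibocyte-like cells and the Krt79-high cluster were lost.

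The 5 settings that had been chosen at the outset and moved the count of genes higher in meibocyte-like than in basal-epithelial-like cells changed which clusters were named basal-epithelial-like, and 51.4 to 53.6% of the genes higher in the reported comparison that were tested again stayed higher. With DESeq2's Wald test 962 genes were higher and 1355 lower for meibocyte-like against basal-epithelial-like cells. The keratin comparison was not run with the plain neighbour graph, where fewer than 2 subclusters qualified, DESeq2 gave no list test, and the 2 planned comparisons with ductal-epithelial-like cells were not run. In meibocyte-like against basal-epithelial-like cells Cd36 lost its call under DESeq2 (adjusted p = 0.163) and Cyp4f39 without replicate 3 (adjusted p = 0.188), and the cause was not tested. Awat1 was too low to test at this depth.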

Other observations

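All tests of patterns and of other splits in this part were chosen only after the results were seen, and no biological explanation was tested, since the labels give no group among the wild-type libraries for it.

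Awat2 in the Krt79-high cluster stood at 28.6%, 31.3% and 40.8% of its meibocyte-like level in replicates 1, 2 and 3. If RNA or cells of the average meibocyte-like profile were the whole source, other genes of that profile should stand at least at that percentage. The 20 most abundant other genes called higher than in basal-epithelial-like cells, at a log2FC of at least 4, were read for this. They were picked from these data and were not particular to meibocyte-like cells, since Sprr1a stood at 356%, 234% and 446%. Their median reached at most 0.451 of that of Awat2 in any library. This argues against free RNA, doublets or misplaced cells of that profile as the whole cause. Against the keratin-low subcluster, which held the most Awat2, the median of the same 20 genes stood at 0.494 to 0.598 of that of Awat2, which decided nothing, and another test was added after that. The median of the other fixed genes at 50 CPM or more in keratin-low cells stood at no more than 0.433 of that of Awat2 in any library. Elovl6 stood at 0.0588 to 0.143 of it, and Soat1, Far2 and Elovl3 lower still, which argues against keratin-low cells or their RNA as the whole cause. Of the other subclusters with at least 20 cells in every library, keratin-high cells and a further subcluster held less Awat2 than the Krt79-high cluster, which held at least 215% and 153% of their levels, so neither can be the whole source. Against the remaining subcluster that median stood at no more than 0.197, which argues against it too. The smallest subcluster was not tested. The 5 cells with most Awat2 UMIs held 23.9% of the cluster's Awat2 UMIs, so whether a few cells carry much of the signal stays open.

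The hair-follicle-like share was 3.60%, 5.57% and 11.2% in replicates 1, 2 and 3. The ratio of this share to that of the basal-epithelial-like cluster, which was high in Lgr5 and Lhx2, differed 2.83-fold between libraries. Whether that cluster belongs to hair follicles was not shown, so more whole follicles in the tissue taken stay open as a cause. The run cannot be told apart from the replicate, because run 2 held 1 wild-type library, and the 2 libraries of run 1 differed 1.55-fold between themselves.

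The share of cluster 5, an unnamed cluster led by Hs3st1, Cldn4 and Cxcl17, was 13.8%, 6.72% and 2.07% in replicates 1, 2 and 3, a 6.66-fold range. Clusters 2 and 19, both led by Gpha2 and Pax6, held 4.57%, 6.37% and 12.4% together. The sum of clusters 2, 5 and 19 was 18.3%, 13.1% and 14.5%, a 1.40-fold range. The shares added run in opposite directions and were picked after they were seen, so an even sum does not decide whether these clusters are 1 population.

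Other splits of the same class sums were fitted to see how many genes they call. For the 4 comparisons of 3 sums against 3 there are 10 splits, 1 of them the real one, and the share is never under 0.1. The real splits called 2357 genes (meibocyte-like against basal-epithelial-like), 1577 (keratin comparison), 1321 (meibocyte-like cells against the Krt79-high cluster) and 1832 (Krt79-high cluster against basal-epithelial-like), and the highest of the other splits called 0 in each. For fibroblast-like cells against the epithelial classes pooled, 100 of 455 splits were drawn, the real split called 1997 genes, the highest other 123, and only 1 split, the real one, reached as many. That fit is not the reported comparison. The classes were built from the expression of the same cells, so the real split was bound to call the most genes, and these counts decide nothing about chance.

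A cycling cluster of 345 cells held meibocyte genes: Plin2 reached 1022 ± 378 CPM, Cidea 98.6 ± 27.3 CPM and Pparg 35.0 ± 4.46 CPM beside Mki67 at 296 ± 80.0 CPM and Top2a at 445 ± 51.3 CPM (n = 3). The other 2 cycling clusters held 14.9 and 17.6 CPM of Plin2. An unnamed cluster of 720 cells, led by Serpine2, F5 and Vcan, held Rspo3 at 1044 ± 131 CPM, Hhip at 727 ± 147 CPM, Bmp4 at 317 ± 12.2 CPM and Ptch1 at 295 ± 45.4 CPM, where the 3 fibroblast-like clusters held 10.7, 18.6 and 23.4 CPM of Rspo3. Hemoglobin genes together took 127, 0.320 and 1161 CPM of all UMIs in replicates 1, 2 and 3.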
